A study of Mus musculus with 6 samples.

How the data were processed

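Poly(A) RNA from pancreatic islets was sequenced in 6 libraries, 3 from mice overfed by gastric infusion for 9 days (OIO) and 3 from mice infused with saline (control). Per the labels' protocols, RNA was extracted with Trizol and libraries were made with an Illumina TruSeq RNA kit, and whether the kit marked strand is not stated. The submitters' processing notes name bcl2fastq, kallisto and limma and the builds GRCm38 and mm10, with no versions, roles or order. The groups and libraries came from the labels, which give no batch, pairing, date or hour of collection. Replicates were numbered in accession order, so the numbers only name libraries. Library codes in the table were written with an extra 0 compared with the labels and were matched by their number.

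The authors deposited a table of whole-number counts for 23420 gene symbols in the 6 libraries, with no normalization. How the estimates of kallisto, named in the submitters' processing notes, became whole counts per gene symbol is not given in the sources used here. The plan written before the data were examined assumed estimated counts to be rounded, and the values were whole already, so none was rounded. A second deposited table held the authors' comparison of the groups, with a log2 fold change, an average log2 expression, a moderated statistic and a log odds as scores, a p-value and an adjusted p-value per gene. Its columns carry the names limma gives them, per the file headers, and its model, filter and direction are not stated there. Kallisto divides reads that fit several transcripts by likelihood, so counts of genes with similar copies (Ins1 and Ins2, ribosomal genes) and of overlapping genes are less certain than others.

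Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the groups, libraries were scaled by trimmed mean of M-values (TMM), and a quasi-likelihood model with robust dispersions was fitted with group as the only term. With 6 libraries the model had 4 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over the 14903 genes tested, with a threshold of 0.05. Expression is given as CPM on the TMM-scaled library sizes, as mean ± SD, and differences as log2 fold change of OIO over control with a standard error (SE). The SE is the absolute log2 fold change divided by the square root of the quasi-likelihood F, and not a separate estimate of the fit. An exact permutation test of 3 against 3 libraries cannot give a 2-sided p under 0.1, so single genes were tested only in the model across genes.

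Before the data were examined, 32 gene lists were fixed for cell cycle, islet, stress, metabolic and signalling genes and for other cell types of the pancreas. Of these, 30 had at least 5 tested members and were tested with camera in limma 3.58.1, with a preset inter-gene correlation of 0.01, 2-sided, and Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation, and fry, were run beside it. Counts of members past the threshold are given over all genes and adjusted over the list alone. Entries with another symbol in the table were matched through synonyms, which applied to 13 of them. List scores per library are the mean over members of log2 CPM minus the control mean.

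Genes were named by a rule fixed before the data were examined. It took the 10 largest rises and 10 largest falls among genes past the threshold with an average log2 CPM of at least 2, a symbol that is not a predicted-gene name, and all libraries of a group on the same side. It also took up to 4 members of lowest p in each list, and always Sin3a, Ins1, Ins2, Mki67, Ccnd2, Pdx1, Mafa, Gcg and Tph1. Slc2a2, Cyp51 and Angptl4 were added after their values were seen, as called members of lists with at most 5 calls, and so were clock genes of a list of 18 written after the data were seen. Coordinates came from the GENCODE mouse annotation, release M21, on GRCm38, the build the notes name. Results for 2 genes that these rules chose are not reported here. A match by symbol was found for 98.4% of the genes in the table.

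The test was run on simulated counts with the means, depths and estimated dispersions of these libraries, in which 200 of 14903 genes were changed. The changed genes were drawn only from genes averaging at least 4 CPM, so the shares do not cover genes of lower expression. The test called 82% of 50 genes changed 1.5-fold, 96% at 2-fold, 100% at 3-fold and 98% at 4-fold, and 14 of 14703 unchanged genes. The simulation held no correlation between genes and so did not test the preset correlation of the list tests. The biological coefficient of variation was 10.4%. Depth ranged from 20968058 counts in OIO replicate 1 to 48178375 in OIO replicate 2. Replicate libraries differed by more than counting noise, with a chi-square per degree of freedom between 13.1 and 52.2. No pair of replicates within a group therefore held the same counts within counting noise, which does not show that the libraries came from separate mice.

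The alternatives fixed before the data were examined were edgeR with relative log expression (RLE), upper-quartile or library-size scaling, DESeq2 1.42.0, limma voom, no filter on low counts, a filter of at least 1 CPM in 3 libraries, dispersions not made robust, thresholds of 0.1 and 0.01, a test against a 1.2-fold change, removal of acinar genes, and leaving out each library. Alternatives chosen after seeing the data corrected for transcript length and GC content, thinned all libraries to the smallest total, removed hormone genes, added the T and B cell, acinar or stellate score as a covariate, or left out OIO replicate 1 and control replicate 3 together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.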

Results

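Polyadenylated RNA was sequenced from the pancreatic islets of C57BL/6J mice, the hormone-secreting clusters that hold the insulin-producing beta cells. Mice labelled OIO, for overfeeding-induced obesity, had received the liquid diet Ensure through a gastric infusion for 9 days at 13 to 18.5 kcal per day. Control mice had received saline by the same route for 9 days. Each group held 3 libraries, and the labels do not say whether each came from a separate mouse, so p-values measure only the spread between these libraries, which may be technical. The counts summed to 20968058, 48178375 and 36437109 in OIO replicates 1, 2 and 3, and to 34103107, 37548350 and 39286793 in control replicates 1, 2 and 3. Ins1, Ins2, Gcg and Iapp, the genes of the main islet hormones, together took between 27.1% and 30.8% of the counts of a library. The series title places the comparison in a study of how the co-repressor Sin3a bears on the growth of beta cell mass after birth, and the libraries address which islet transcripts differ after overfeeding.

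In islets of overfed mice, 34 of 40 tested genes of DNA replication, 37 of 45 of mitosis and 17 of 33 of protein folding in the endoplasmic reticulum (ER) were higher. Each of these lists passed its test with a preset correlation and had an adjusted p = 0.22 with an estimated correlation. With fry their adjusted p were 0.0097, 0.019 and 0.011. Mcm5, a subunit of the replicative helicase, averaged 22.2 ± 2.01 CPM (mean ± SD, n = 3) in OIO and 6.07 ± 1.67 (n = 3) in control islets. Creld2, an ER stress-induced protein, averaged 151 ± 10.4 against 60.1 ± 3.03 CPM. Nr1d1, which encodes the transcriptional repressor REV-ERB alpha, averaged 11.7 ± 1.37 against 72.3 ± 19.7 CPM and had the largest fall among the named genes. Of 14903 genes tested, 676 were higher and 423 lower in OIO islets at an adjusted p under 0.05, or 1099 in all. At least a 2-fold difference was reached by 160 of the higher and 14 of the lower genes. The groups did not overlap for 4364 genes, or 29.3% of those tested, where chance gives 10%. The balance of the calls reversed when libraries were scaled by size alone, which gave 498 higher and 1113 lower genes. The median of all genes was then at −0.08 on the log2 scale. Higher calls stayed the majority with RLE (693 higher, 369 lower), upper-quartile scaling (693 and 393), DESeq2 (891 and 504) and limma voom (640 and 346). The number of calls was 513, 460 and 506 without OIO replicate 1, 2 or 3 and 701 without control replicate 2. The higher calls numbered 401, 336, 356 and 440 in these fits. The lower calls numbered 112, 124, 150 and 261, and 257 without control replicate 1. Without OIO replicate 1, the shallowest, and control replicate 3 together, a choice made after seeing the data, 457 genes were higher and 142 lower.

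**Figure D1:**
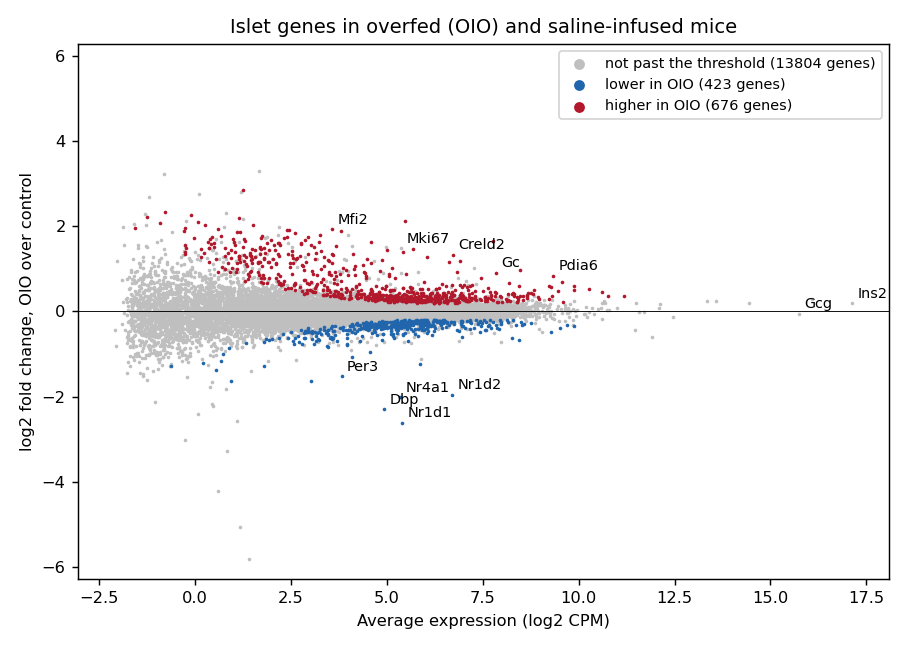
Each point is 1 of 14903 tested genes, with average expression in log2 CPM on the horizontal axis and the log2 fold change of OIO over control on the vertical axis, from 3 libraries per group. Red points mark the 676 genes higher and blue points the 423 genes lower in OIO at an adjusted p under 0.05, grey points did not pass, and Nr1d1 at −2.61 and Mfi2 at 1.92 are among the labelled genes.

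Most genes of DNA replication and mitosis rose. Of 40 replication genes tested, 34 rose and 6 did not pass, with a median log2 fold change of 0.96, and 38 rose when adjusted over the list alone. Of 45 mitosis genes, 37 rose and 8 did not pass, with a median of 1.34, and 44 rose when adjusted over the list alone. No member of either list fell. Among the replication genes, Mcm5 rose by 1.88 (SE 0.18, adjusted p = 0.0011), Mcm6 by 1.02 (SE 0.09, adjusted p = 2.7e-04) and Rrm1, a subunit of ribonucleotide reductase, by 0.77 (SE 0.07, adjusted p = 4.3e-04). Among the mitosis genes, Cenpe, a kinetochore motor, averaged 9.64 ± 0.55 CPM in OIO and 2.68 ± 0.82 in control islets, a rise of 1.85 (SE 0.20, adjusted p = 0.0011). Cdc20, an activator of the anaphase-promoting complex, rose by 1.60 (SE 0.14, adjusted p = 3.0e-04). Every OIO library lay above every control library in the mean score of each list, and control replicate 2 had the lowest scores, at −0.24 for replication and −0.52 for mitosis against the control mean. With camera and a preset correlation the replication list had an adjusted p of 3.1e-67 and the mitosis list 1.1e-66. Each had an adjusted p = 0.22 with an estimated correlation. T and B cell markers had a median log2 fold change of 0.74 without passing their test (adjusted p = 0.16), and their score was 1.86 and 1.14 in OIO replicates 2 and 3 and 1.60 in control replicate 3, against the control mean.

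Mki67, the gene of the proliferation marker Ki-67, averaged 61.3 ± 3.47 CPM in OIO (n = 3) and 22.0 ± 8.13 in control islets (n = 3), and all 3 OIO libraries lay above all 3 control libraries. Its log2 fold change of 1.48 (SE 0.30) did not pass in edgeR's quasi-likelihood test (adjusted p = 0.059). It passed without control replicate 1 (adjusted p = 0.035) and without control replicate 2 (adjusted p = 0.0014). It also passed in DESeq2 (adjusted p = 2.0e-04), in limma voom (adjusted p = 0.0049) and when scaled by library size alone (adjusted p = 0.044). In the authors' deposited table its log2 fold change was 1.56 with an adjusted p of 0.010.

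Of 23 G1 cyclins and growth regulators, none rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.95). These were Pik3r1, a regulatory subunit of phosphoinositide 3-kinase, at −0.38 (SE 0.06, adjusted p = 0.0064), and Ccnd2, the gene of cyclin D2, at −0.33 (SE 0.09, adjusted p = 0.048). The median of that list was 0.03, opposite in sign to its test, and −0.04 when scaled by library size alone. Ccnd2 did not pass without OIO replicate 1 or 2 or control replicate 1 or 3 (adjusted p between 0.11 and 0.18). Of 16 cell cycle inhibitors, 3 rose and none fell, also when adjusted over the list alone. They were Cdkn2c at 0.51 (adjusted p = 0.021), Rbl1 at 0.50 (adjusted p = 0.010) and Ccng1 at 0.24 (adjusted p = 0.045). Cdkn2c did not pass without OIO replicate 2 or 3 or control replicate 2 (adjusted p 0.079, 0.069 and 0.052), and Ccng1 passed in none of the fits that left out a library (highest adjusted p 0.13). The inhibitor list had a camera adjusted p of 0.046 and an adjusted p = 0.39 with an estimated correlation. It was 0.11 without control replicate 1 and 0.098 without control replicate 3.

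Among the genes named for the size of their rise, Mfi2, now named Meltf and encoding melanotransferrin, rose by 1.92 (SE 0.10, adjusted p = 6.6e-06), from 4.97 ± 0.46 to 18.8 ± 0.34 CPM. A further 8 rose by between 1.73 and 1.91 and were Uhrf1, Pole, Mcm5, Cenpe, Slfn9, Nek2, Hells and Ube2c. Of these, Nek2 did not pass without OIO replicate 1, 2 or 3 or control replicate 3 (adjusted p 0.058, 0.059, 0.059 and 0.065). The largest falls were in Nr1d1 at −2.61 (SE 0.22, adjusted p = 0.0043), Dbp at −2.30 (SE 0.14, adjusted p = 2.6e-04), Nr4a1 at −2.01 (SE 0.28, adjusted p = 0.022) and Nr1d2 at −1.96 (SE 0.07, adjusted p = 3.8e-07). Sik1, Per3, Tef, Adamts1, Coq10b and Dusp4 followed, between −1.64 and −0.84. Nr1d1, Nr1d2, Dbp, Tef and Per3 belong to the circadian clock or its direct output, and Nr1d1 overlaps Thra on the opposite strand. Sik1 did not pass without OIO replicate 1 (adjusted p = 0.068), and Coq10b did not pass without OIO replicate 1 or 2 (adjusted p 0.062 and 0.065). By the rule that chose them, all 3 OIO libraries lay on the same side of all 3 control libraries for each of these genes.

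In GRCm38, Mfi2 lies on chromosome 16 from 31878810 to 31899020 and Mcm5 on chromosome 8 from 75109569 to 75128439. Nr1d1 lies on chromosome 11 from 98767932 to 98775333, Nr1d2 on chromosome 14 from 18204054 to 18239127, and Dbp on chromosome 7 from 45705088 to 45710203. Creld2 lies on chromosome 15 from 88819646 to 88826683, Mki67 on chromosome 7 from 135689784 to 135716361, and Sin3a on chromosome 9 from 57072040 to 57128366. All are annotated as protein-coding genes, and the counts are per gene and do not separate exons or untranslated regions.

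Of 33 tested genes of protein folding in the ER, 17 rose, none fell and 16 did not pass, with a median log2 fold change of 0.25, and adjusted over the list alone 18 rose and 2 fell. Creld2 rose by 1.33 (SE 0.07, adjusted p = 6.6e-06) and Sdf2l1, an ER chaperone component, by 1.16 (SE 0.09, adjusted p = 2.7e-04). Pdia6, a protein disulfide isomerase, averaged 827 ± 17.9 CPM in OIO and 463 ± 16.3 in control islets, a rise of 0.84 (SE 0.06, adjusted p = 3.8e-05). Ssr4, part of the translocon-associated complex, rose by 0.66 (SE 0.06, adjusted p = 5.5e-04). The ER list had a camera adjusted p of 2.7e-20 and an adjusted p = 0.22 with an estimated correlation.

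Of 31 targets of ATF4, the transcription factor of the integrated stress response, Psat1, an enzyme of serine synthesis, rose by 0.98 (SE 0.10, adjusted p = 5.6e-04) and Ppp1r15a, a phosphatase subunit that restores translation after stress, fell by 0.41 (SE 0.07, adjusted p = 0.0062). Adjusted over the list alone, 1 rose and 2 fell. Over all genes, 2 rose without OIO replicate 2, 4 without control replicate 2 and 1 in each other fit that left out a library, and 3 rose in DESeq2. The median of the list was 0.13, with a camera adjusted p of 0.043 and an adjusted p = 0.79 with an estimated correlation. Its camera adjusted p was 0.37 without OIO replicate 3, 0.12 without control replicate 1 and 0.15 without control replicate 3.

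Of 31 tested genes of the secretory granule and of exocytosis, 8 rose and none fell, with a median of 0.08, and 10 rose when adjusted over the list alone. Scaled by library size alone, 5 rose and 4 fell. Vgf, a granule protein precursor, rose by 0.995 (SE 0.16, adjusted p = 0.012), Ptprn, a membrane protein of the granule, by 0.59 (SE 0.08, adjusted p = 0.0021), Pcsk1, a prohormone convertase, by 0.48 (SE 0.09, adjusted p = 0.013) and Syt5 by 0.46 (SE 0.07, adjusted p = 0.0039). The list had a camera adjusted p of 0.0039 and an adjusted p = 0.62 with an estimated correlation. The number that rose was 5 without OIO replicate 2 or control replicate 2 and 4 without OIO replicate 3 or control replicate 3. Without OIO replicate 3, 1 granule gene also fell.

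Insulin transcripts did not pass the test. Ins1 averaged 76241 ± 2758 CPM in OIO and 62617 ± 7303 in control islets (log2 fold change 0.28, SE 0.09, adjusted p = 0.078, and 0.0043 in DESeq2), and Ins2 had 0.19 (SE 0.11, adjusted p = 0.33). These genes are closely related copies, so how reads that fit both were divided between them is uncertain. Of 27 genes of beta cell identity and maturity, 2 rose and 3 fell, and adjusted over the list alone 5 rose and 4 fell (camera adjusted p = 0.64). The median was 0.01, and −0.05 when scaled by library size alone. Ffar1, a fatty acid receptor, rose by 0.57 (SE 0.06, adjusted p = 6.1e-04), as did Pcsk1. Slc30a8, the granule zinc transporter, was at −0.35 (adjusted p = 0.023), Isl1 at −0.39 (adjusted p = 0.044) and Slc2a2, the glucose transporter GLUT2, at −0.39 (adjusted p = 0.044). Slc2a2 was named after its value was seen. Slc30a8 passed without control replicate 2, Isl1 without control replicate 3 and Slc2a2 without OIO replicate 2, and none of the 3 passed in the other fits that left out a library (highest adjusted p 0.094, 0.14 and 0.14). The transcription factors Pdx1 at −0.08 (adjusted p = 0.73) and Mafa at −0.14 (adjusted p = 0.29) did not pass. None of 23 disallowed and dedifferentiation genes passed, also when adjusted over the list alone (camera adjusted p = 0.995), where the median of −0.06 and the mean of 0.00 differed in sign.

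Markers of the other endocrine cells held few calls. The list of 12 alpha cell genes did not pass (camera adjusted p = 0.68). The median of that list was −0.01 and its mean 0.01, and the median was 0.00 in limma voom. Gcg, the glucagon gene, had a log2 fold change of −0.05 (SE 0.25, adjusted p = 0.93) and took 8.02% of the counts in control replicate 2 against 4.29% to 5.72% in the other libraries. Of 10 delta and PP cell genes, Ghsr, the ghrelin receptor, rose by 0.74 (SE 0.13, adjusted p = 0.011), also over the list alone, and 9 did not pass (camera adjusted p = 0.74, median −0.06).

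**Figure D2:**
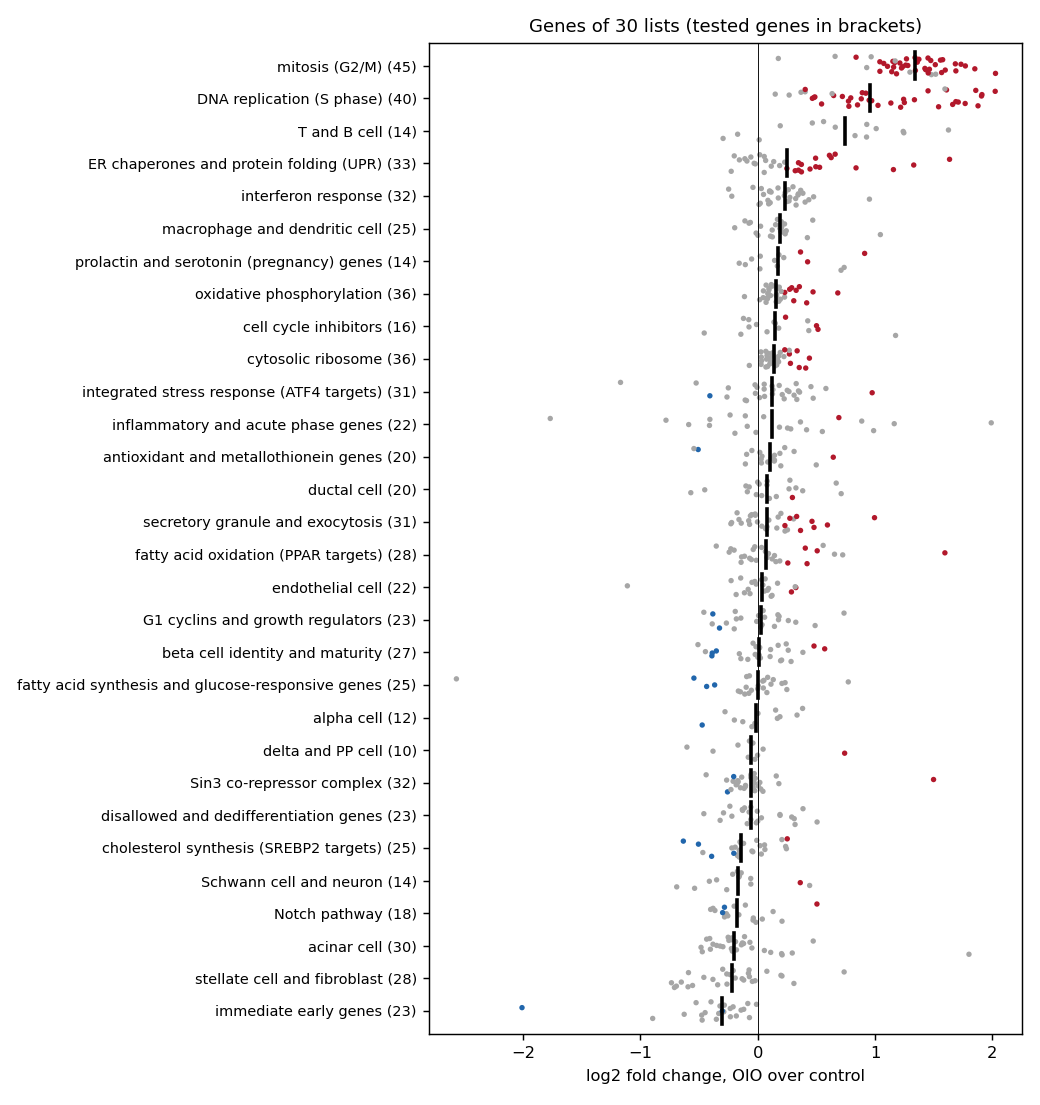
Each point is a tested gene of 1 of 30 gene lists, placed by its log2 fold change of OIO over control from 3 libraries per group, and the black bar is the median of the list. Red and blue points are genes higher and lower at an adjusted p under 0.05 and grey points did not pass, and the medians reach 1.34 for mitosis and 0.96 for DNA replication and lie between −0.30 and 0.74 for the other lists.

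A minority of the genes of mitochondrial respiration and of the cytosolic ribosome rose. Of 36 genes of oxidative phosphorylation, 9 rose and none fell, with a median of 0.16, and 19 rose when adjusted over the list alone. Scaled by library size alone, 6 rose and 1 fell, with a median of 0.09. Uqcrq, a subunit of complex III, rose by 0.68 (SE 0.07, adjusted p = 5.3e-04) and Cox5b, of complex IV, by 0.33 (SE 0.06, adjusted p = 0.0091). The number that rose was 3 without OIO replicate 2, 4 without OIO replicate 3 or control replicate 1 and 5 without control replicate 2. The list had a camera adjusted p of 2.9e-09 and an adjusted p = 0.34 with an estimated correlation. Of 36 ribosomal genes, 7 rose and none fell, with a median of 0.14, and 10 rose when adjusted over the list alone. Scaled by library size alone, 3 rose and none fell, with a median of 0.07. Rps2 rose by 0.44 (SE 0.06, adjusted p = 0.0028) and Rplp0 by 0.41 (SE 0.05, adjusted p = 0.0024), although ribosomal genes have many processed copies that can share their reads. The number that rose was 3 without OIO replicate 1 or control replicate 1 or 2 and 4 without OIO replicate 2 or 3. That list had a camera adjusted p of 2.3e-06 and an adjusted p = 0.62 with an estimated correlation. Fold changes fell with transcript length over genes with a known length and an average log2 CPM of at least 2 (Spearman −0.18 across genes, which are not independent replicates). With length and GC content corrected the medians were 0.12 for respiration and 0.09 for the ribosome.

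Some genes of fatty acid oxidation rose and some of cholesterol synthesis fell. Of 28 fatty acid oxidation genes, 5 rose and none fell, with a median of 0.07, and 7 rose when adjusted over the list alone. With library size alone as the scaling, 4 rose and 1 fell, and the median was 0.01. Cpt1a, the gate of mitochondrial fatty acid entry, rose by 0.42 (SE 0.07, adjusted p = 0.0082) and Slc25a20, the carnitine carrier, by 0.41 (SE 0.07, adjusted p = 0.010). Plin2, a lipid droplet coat protein, rose by 0.51 (SE 0.11, adjusted p = 0.022), Cpt2 by 0.26 (adjusted p = 0.027), and Angptl4, a lipase inhibitor named after its value was seen, by 1.60 (SE 0.35, adjusted p = 0.033). When a library was left out, Plin2 passed only without OIO replicate 3 or control replicate 2 (highest adjusted p 0.079) and Cpt2 only without control replicate 1 (highest adjusted p 0.079). Angptl4 did not pass without control replicate 1, 2 or 3 (adjusted p 0.12, 0.11 and 0.0996). The list had a camera adjusted p of 0.025, 0.070 without control replicate 1 and 0.056 without control replicate 3, and an adjusted p = 0.42 with an estimated correlation. The number that rose was 3 without OIO replicate 1 or 2 or control replicate 1 and 2 without control replicate 3.

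Of 25 cholesterol synthesis genes, 4 fell and 1 rose, with a median of −0.15, and adjusted over the list alone 5 fell and 1 rose. With library size alone as the scaling, 7 fell and none rose, and the median was −0.21. Hmgcs1, which makes the precursor of mevalonate, fell by 0.39 (SE 0.06, adjusted p = 0.0046), Sc4mol, now named Msmo1, by 0.51 (SE 0.08, adjusted p = 0.0067) and Hsd17b7 by 0.63 (SE 0.13, adjusted p = 0.018). Cyp51, named after its value was seen, was at −0.20 (adjusted p = 0.047), and Ebp rose by 0.25 (adjusted p = 0.037). Cyp51 and Ebp passed in none of the fits that left out a library (highest adjusted p 0.19 and 0.12), and Hsd17b7 did not pass without OIO replicate 1 or 3 or control replicate 1 (adjusted p 0.059, 0.066 and 0.053). The list had a camera adjusted p of 0.021 and an adjusted p = 0.24 with an estimated correlation. Of 25 genes of fatty acid synthesis and glucose response, 3 fell and none rose, also when adjusted over the list alone (camera adjusted p = 0.64, median 0.00). They were Khk, or ketohexokinase, at −0.54 (SE 0.10, adjusted p = 0.010), Mlxipl, which encodes the glucose-responsive factor ChREBP, at −0.44 (adjusted p = 0.035) and its target Arrdc4 at −0.37 (adjusted p = 0.038). When a library was left out, Mlxipl passed only without control replicate 3 (highest adjusted p 0.12) and Arrdc4 only without OIO replicate 1 or control replicate 3 (highest adjusted p 0.14).

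Few immediate early genes passed the test. All 23 tested had a negative log2 fold change, with a median of −0.30, of which 2 passed and 3 did when adjusted over the list alone. The number that fell was 0 without OIO replicate 1 or 3 or control replicate 3, and 1 without OIO replicate 2 or control replicate 2. Nr4a1, an activity-induced nuclear receptor, averaged 16.2 ± 1.60 CPM in OIO and 64.7 ± 21.9 in control islets, and Ier5 was at −0.30 (SE 0.08, adjusted p = 0.044). Nr4a1 did not pass without OIO replicate 1, 2 or 3 or control replicate 3 (adjusted p 0.097, 0.10, 0.089 and 0.055), and Ier5 passed only without OIO replicate 2 (highest adjusted p 0.16). The list had a camera adjusted p of 1.3e-05 and an adjusted p = 0.28 with an estimated correlation. Among 20 antioxidant and metallothionein genes, Gpx1, a glutathione peroxidase, rose by 0.64 (SE 0.06, adjusted p = 5.1e-04) and Gstm1 fell by 0.51 (SE 0.07, adjusted p = 0.0037), also when adjusted over the list alone. The list did not pass (camera adjusted p = 0.17, median 0.10), although it did without OIO replicate 2 (adjusted p = 0.029). With all libraries and an estimated correlation it had an adjusted p of 0.62.

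The list of prolactin and serotonin genes, drawn up for islets in pregnancy, had 14 tested members. Of these, 3 rose and none fell, with 4 rising when adjusted over the list alone. The list mixes receptors and signalling genes such as Prlr and Stat5a with others, so it does not measure a pregnancy-type induction. Gc, which encodes the vitamin D binding protein, averaged 298 ± 16.5 CPM in OIO and 158 ± 11.6 in control islets, a rise of 0.91 (SE 0.07, adjusted p = 1.0e-04). Igfals rose by 0.43 (SE 0.08, adjusted p = 0.011) and Chgb, a granin, by 0.36 (SE 0.08, adjusted p = 0.027). Chgb did not pass without OIO replicate 1 or 3 or control replicate 1 or 3 (adjusted p 0.087, 0.064, 0.078 and 0.065). Tph1, a serotonin synthesis enzyme of that list, had between 0 and 22 counts per library and was not tested. The list median was 0.17, with a camera adjusted p of 5.4e-04 and an adjusted p = 0.22 with an estimated correlation.

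Sin3a averaged 75.1 ± 3.69 CPM in OIO (n = 3) and 89.7 ± 5.03 in control islets (n = 3), and all 3 OIO libraries lay below all 3 control libraries. Its log2 fold change was −0.26 (SE 0.06, adjusted p = 0.032). In the authors' deposited table it was −0.26 with an adjusted p of 0.052. Sin3a passed without control replicate 3 and did not without OIO replicate 1, 2 or 3 (adjusted p 0.059, 0.13 and 0.12) or control replicate 1 or 2 (adjusted p 0.081 and 0.10). Of 32 genes of the Sin3 co-repressor complex and its partners, Mxd3 rose by 1.5 (SE 0.30, adjusted p = 0.017) and Sin3a and Max, the partner of MYC and MXD proteins, at −0.20 (SE 0.05, adjusted p = 0.038), fell. Adjusted over the list alone, 1 rose and 5 fell, and scaled by library size alone 1 rose and 7 fell. Mxd3 did not pass without OIO replicate 2 (adjusted p = 0.069), and Max passed in none of the fits that left out a library (highest adjusted p 0.17). The list had a median of −0.06, a camera adjusted p of 0.0495 and an adjusted p = 0.40 with an estimated correlation. Its camera adjusted p was 0.13 without OIO replicate 1, 0.15 without control replicate 1 and 0.11 without control replicate 2.

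Of 18 Notch pathway genes, Dtx1 rose by 0.50 (SE 0.09, adjusted p = 0.013), and Rbpj at −0.28 (adjusted p = 0.027) and Hes6 at −0.30 (adjusted p = 0.046) fell. Adjusted over the list alone, 1 rose and 3 fell, and the list did not pass (camera adjusted p = 0.067, median −0.18), although it passed as lower without OIO replicate 1 (adjusted p = 0.0061) and in limma voom (adjusted p = 0.027). With all libraries and an estimated correlation the Notch list had a camera adjusted p of 0.62. Scaled by library size alone, 1 gene rose and 4 fell. Dtx1 did not pass without OIO replicate 3 (adjusted p = 0.053). Of the 6 fits that left out a library, Rbpj and Hes6 each passed only in the one without control replicate 2, with a highest adjusted p of 0.10 and 0.15. The number that fell was 0 without OIO replicate 1, 2 or 3 or control replicate 1, and 1 without control replicate 3.

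**Figure D3:**
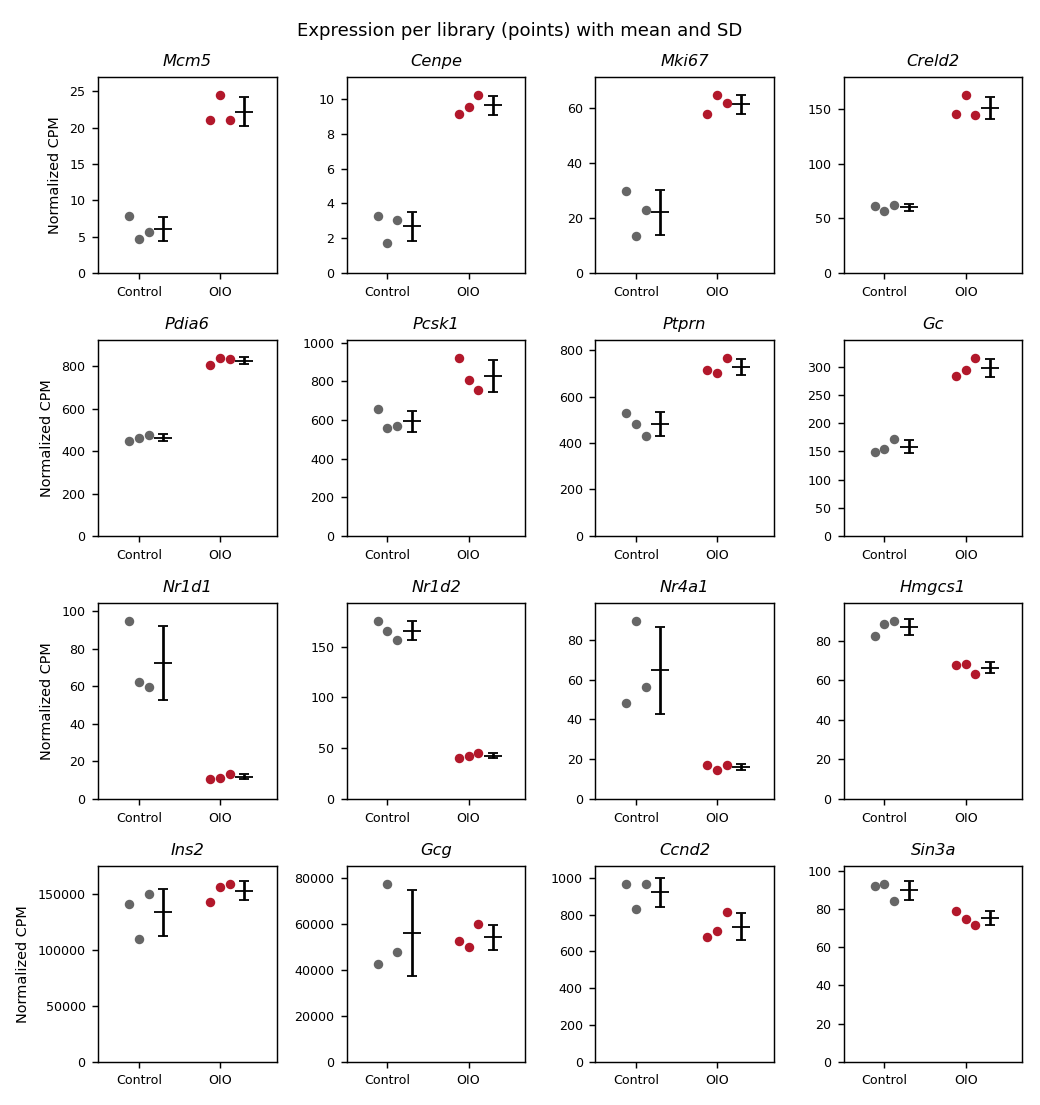
Normalized expression in CPM (vertical axes from 0) of 16 named genes in the 3 control libraries (grey) and the 3 OIO libraries (red), with the mean and SD as a bar beside each group. Mcm5 averaged 22.2 CPM in OIO and 6.07 in control islets, Nr1d1 averaged 11.7 and 72.3, and Sin3a averaged 75.1 and 89.7.

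Immune genes held few calls. None of 32 interferon response genes passed, also when adjusted over the list alone, although 29 had a positive log2 fold change, with a median of 0.23. That list had a camera adjusted p of 0.0048, 0.11 without OIO replicate 1, and an adjusted p = 0.62 with an estimated correlation, and its score was highest in OIO replicate 1, at 0.38 against the control mean. Of 22 inflammatory and acute phase genes, Il1r1, the interleukin-1 receptor, rose by 0.69 (SE 0.09, adjusted p = 0.0026), from 584 ± 40.3 to 943 ± 116 CPM, also over the list alone. Lcn2, an acute phase protein, had a log2 fold change of 1.99 (SE 0.51) that did not pass (adjusted p = 0.080), and it passed without OIO replicate 3 (adjusted p = 0.0042) and in DESeq2 (adjusted p = 0.0062). The inflammatory list did not pass (camera adjusted p = 0.20, median 0.12), and it passed without OIO replicate 2 (adjusted p = 0.029). With all libraries and an estimated correlation it had an adjusted p of 0.79. No gene passed among 25 of macrophages and dendritic cells (camera adjusted p = 0.052, median 0.19) or 14 of T and B cells (adjusted p = 0.16), also over the lists alone. Without control replicate 3, whose T and B cell score was 1.60 against the control mean, these lists passed as higher with adjusted p of 2.0e-05 and 2.8e-05, and 4 macrophage genes rose. Without OIO replicate 1 and control replicate 3 together, a choice made after seeing the data, 3 of the macrophage and 6 of the T and B cell genes rose. The T and B cell score of OIO replicate 1 was −0.24, against 1.86 and 1.14 in OIO replicates 2 and 3. Leaving out these libraries thus widened the difference in that score by itself, so the T and B cell calls are no separate evidence. The macrophage list also passed without OIO replicate 2 (adjusted p = 0.0015) and without OIO replicate 3 (adjusted p = 0.038), and the T and B cell list without OIO replicate 1 (adjusted p = 0.019). In limma voom the lists passed with adjusted p of 0.045 and 0.015. All these list tests used the preset correlation. With all libraries, the macrophage and the T and B cell list had an adjusted p of 0.87 and 0.88 with an estimated correlation. With fry they had 0.53 and 0.60.

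Markers of other pancreatic cell types varied between libraries within each group. No acinar gene of 30 passed, also over the list alone (camera adjusted p = 0.68, median −0.20), and the acinar score was 0.71 in OIO replicate 1, 0.87 in control replicate 1 and −0.81 in control replicate 3, against the control mean. The acinar list passed as lower without OIO replicate 1 (adjusted p = 0.019) and as higher without control replicate 1 (adjusted p = 0.049). No stellate cell and fibroblast gene of 28 passed, also over the list alone (camera adjusted p = 0.33, median −0.22), and control replicate 3 had the highest score, at 0.64. That list passed as lower without OIO replicate 1 (adjusted p = 0.0061) and without control replicate 1 (adjusted p = 0.049). Of 22 endothelial genes, Eng at 0.32 (adjusted p = 0.047) and Tek at 0.29 (adjusted p = 0.0496) rose, also over the list alone, whereas none rose and 1 fell when scaled by library size alone. Tek passed in none of the fits that left out a library and Eng in 1 (highest adjusted p 0.14 for each). The endothelial list did not pass (camera adjusted p = 0.68), with a median of 0.04, a mean of −0.01 and a median of −0.03 under library size alone. Of 20 ductal genes, Krt7, a keratin, rose by 0.30 (SE 0.06, adjusted p = 0.020), also over the list alone (camera adjusted p = 0.27, median 0.08), and did not pass without OIO replicate 3 or control replicate 2 (adjusted p = 0.059 for each). Of 14 Schwann cell and neuron genes, Mbp, a myelin protein, rose by 0.36 (SE 0.06, adjusted p = 0.0059), and over the list alone 1 rose and 1 fell (camera adjusted p = 0.31, median −0.17). That list passed as lower without OIO replicate 1 (adjusted p = 0.027) and without control replicate 1 (adjusted p = 0.035). The fits in which the acinar, stellate and Schwann cell lists passed used the preset correlation. With all libraries and an estimated correlation, camera gave an adjusted p of 0.96 for the acinar and stellate lists and 0.88 for the Schwann cell list. Only 2 adipocyte and 2 erythrocyte genes were tested, with no set test. None of the 4 passed over all genes, and over the lists alone 1 adipocyte gene rose and 1 fell.

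In the authors' deposited table, 900 of the same 14903 genes had an adjusted p under 0.05, of which 590 had a positive and 310 a negative log2 fold change. The calls shared with the edgeR test numbered 870, all with the same sign, while 229 genes passed only in the edgeR test and 30 only in the authors' deposited table. Over genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.968 and a Spearman rho of 0.988. The table's header does not state the direction of its fold changes, which matched OIO minus control.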

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

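The length and GC correction, thinning, hormone gene removal, cell type covariates and the joint omission of OIO replicate 1 and control replicate 3 were chosen after the results were seen. No paired analysis was possible because the replicate numbers only name the libraries. Of 94 named genes past the threshold, none changed sign under any alternative, 61 passed in every fit that left out 1 library, and 82 passed under RLE, upper-quartile and library-size scaling, DESeq2 and limma voom. Many of these genes were chosen for a low p or separated groups in the same data, so a change of sign was unlikely from the outset. Causes were not tested except where fewer libraries or a stricter threshold made the change. At these depths and with 3 libraries per group, 82% of genes with a simulated 1.5-fold change were called, a share that covers no genes of low expression. After thinning to the smallest library 964 genes passed.

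The 1099 calls became 1062 with RLE, 1086 with upper-quartile scaling, 1395 with DESeq2, 986 with limma voom, 1086 with no filter and 1139 with the stricter filter. Scaling by library size alone gave 1611, of which 498 were higher and 1113 lower. An adjusted p under 0.1 gave 1890 (1052 higher, 838 lower), and one under 0.01 gave 274 (208 higher, 66 lower), with 22 mitosis genes. A test against a 1.2-fold change gave 191 (164 higher, 27 lower), with 10 ER genes. The T and B cell covariate left 279 lower calls. Without OIO replicate 1 and control replicate 3 there were 599 calls, of which 142 were lower. Leaving out 1 library gave 460 (without OIO replicate 2) to 817 (without control replicate 1) calls, 336 to 560 higher and 112 (without OIO replicate 1) to 303 lower.

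With an estimated correlation 0 of 30 lists passed, against 14 with the preset one. The adjusted p was 0.22 for replication, mitosis, ER and prolactin genes, 0.24 for cholesterol, 0.28 for immediate early, 0.34 for respiration, 0.39 for cell cycle inhibitors, 0.40 for the Sin3 complex, 0.42 for fatty acid oxidation, 0.62 for granule, ribosome and interferon, and 0.79 for ATF4 target genes. With fry 6 lists passed, with an adjusted p of 0.0097 for replication, 0.019 for mitosis, 0.011 for ER, 0.0031 for cholesterol, 0.0295 for respiration and 0.0092 for prolactin genes. For the other lists that passed with the preset correlation, the adjusted p with fry was 0.053 for inhibitors, 0.053 for fatty acid oxidation, 0.053 for immediate early genes, 0.11 for the Sin3 complex, 0.14 for granule genes, 0.15 for the ribosome, 0.22 for interferon and 0.40 for ATF4 targets.

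The Sin3 list had an adjusted p of 0.055 with RLE, 0.056 with the stricter filter, 0.062 with length and GC corrected, 0.063 after thinning, 0.052 without hormone genes, 0.11 with the T and B cell covariate and 0.051 with the acinar covariate. The inhibitor list had 0.052 with the stricter filter, 0.075 after thinning, 0.059 and 0.068 with the acinar and stellate covariates, and 0.082 without OIO replicate 1 and control replicate 3. ATF4 targets had 0.13 with length and GC corrected, 0.054 after thinning, 0.051 and 0.074 with the acinar and stellate covariates, and 0.24 without those 2 libraries. Fatty acid oxidation had 0.0502 with length and GC corrected and 0.059 after thinning. The acinar list, lower and not past the threshold, was higher with the T and B cell covariate (2.0e-04) and without control replicate 1 (0.049).

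Over the fits that left out 1 library, the adjusted p ranged from 0.021 to 0.11 for inhibitors, 5.4e-04 to 0.37 for ATF4 targets, 0.0013 to 0.070 for fatty acid oxidation, 0.011 to 0.15 for the Sin3 complex and 9.1e-05 to 0.11 for interferon genes, and the acinar list from 0.019 to 0.94. The libraries behind the lost calls were OIO replicate 1 (interferon and Sin3), OIO replicate 3 (ATF4), control replicate 1 (inhibitors, ATF4, fatty acid oxidation, Sin3), control replicate 2 (Sin3) and control replicate 3 (inhibitors, ATF4, fatty acid oxidation).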

Other observations

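The clock gene list and the tests of clock phase and of the hour of collection were chosen after the result was seen, as were the length and GC correction, thinning and cell type covariates that the other tests use. Clock genes moved in opposite directions. Of 18 tested, 13 passed. Arntl, which encodes the activator BMAL1, rose by 1.22 (SE 0.14, adjusted p = 0.0022), Npas2, its partner, by 1.62 (SE 0.17, adjusted p = 9.6e-04) and Cry1, a repressor, by 1.35 (SE 0.14, adjusted p = 0.0014), beside Nfil3 at 1.14. Nfil3 did not pass without OIO replicate 2 or 3 or control replicate 1 (adjusted p 0.059, 0.051 and 0.068). Hlf fell by 0.82, Bhlhe40 by 0.69 and Bhlhe41 by 0.58, beside Nr1d1, Nr1d2, Dbp, Tef and Per3. Per1 (−0.61, adjusted p = 0.53), Per2 (−0.09, adjusted p = 0.56), Clock (0.18, adjusted p = 0.070), Usp2 (0.47, adjusted p = 0.20) and Gm129, now named Ciart (−1.03, adjusted p = 0.078), did not pass.

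The clock genes may mark a different clock phase in the groups. All 13 of the 13 clock genes past the threshold had the sign that a shift of phase predicts, in a test on genes picked after some of them had been seen. That test accepted a shift in either direction and left out the genes that did not pass, which made a match easier. After the correction for length and GC content 13 of 13 still passed, which argues against that bias as the whole cause. Whether the hour of collection or the feeding itself set the difference cannot be told apart, because 0 of 6 samples have a label with an hour of collection, and overfeeding stays open and untested.

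The rise of replication and mitosis genes could come from dividing islet cells or from other dividing cells in the preparation. With the T and B cell score as a covariate the median log2 fold change of the 85 genes was 1.19 against 1.24 without it, and 62 of the 71 called genes still passed. The median was 1.24 with the acinar and 1.26 with the stellate score, with 69 and 67 called genes still passing. After thinning to the smallest depth 71 of 71 passed. The values with the T and B cell covariate argue against differing amounts of lymphocytes as the whole cause. The acinar score was 0.71, −0.50 and −0.24 in OIO and 0.87, −0.06 and −0.81 in control replicates 1, 2 and 3. The stellate score overlapped between the groups too, and the shallowest and the deepest library were both OIO. The acinar and stellate covariates and thinning could therefore hardly have removed a difference between the groups, and no conclusion is drawn from them. A score follows the amount of a cell type, so it cannot show whether more cells of that type were dividing. Macrophage, endothelial and ductal scores were not used as covariates. Which islet cells carried the rise stays open, since bulk RNA does not separate cell types, and overfeeding was not separated from other differences between the groups.

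The higher medians of respiratory chain and ribosomal genes may come in part from a trend with transcript length. Length had a Spearman correlation of −0.18 with the fold change over genes with an average log2 CPM of at least 2. With length and GC content corrected the median fell from 0.16 to 0.12 for the respiratory chain and from 0.139 to 0.092 for the ribosome. Their camera adjusted p with the preset correlation were then 2.0e-06 and 0.0012, against 2.9e-09 and 2.3e-06 without the length and GC correction. Also without it, they had an adjusted p = 0.34 and an adjusted p = 0.62 with an estimated correlation. The corrected medians lay between the bounds set for either answer, so a biological difference and the length trend cannot be told apart for these lists.

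Other splits of the 6 libraries into groups of 3 tested the counts. The real split gave 1099 genes and the highest other 7, so 1 of the 10 splits gave as many, and 10 splits are too few for a share under 0.05. For gene lists with the preset correlation, the real split gave 14, 4 of the 10 splits gave as many, and the highest other gave 20, so such list tests also pass in splits that mix the groups. The splits with 19 or 20 lists each placed OIO replicate 1 and control replicate 3 in the same group.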
